A study of Rattus norvegicus with 304 samples.

How the data were processed

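Liver total RNA of rats was reverse transcribed and run as real-time PCR on the OpenArray or the 7900HT, per the labels' protocols, which state a comparative delta-delta Ct setting for the 7900HT only. The deposited fold change tables hold, per the file headers, a gene, a strain, a time, a dose and 1 value for each group. As deposited, it was taken to be the log2 ratio that the authors had computed between a group and corn oil at 19 h of the same strain, where it is 0 for every gene, although no header states the log base. The authors' reference genes, their handling of wells without amplification and their averaging over animals are not given in the sources used here. Per the submitters' processing notes, R 2.12.2 was used. The deposited tables hold 1759 of 1764 possible values on the OpenArray and 1398 of 1404 on the 7900HT, and listed gaps were left missing. An ending on 4 gene names, whose meaning is not stated, was removed.

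The tables of raw cycle values have 150 OpenArray and 154 7900HT columns, 304 in all, whose animal codes match no sample title or description. None of these columns was used. From those tables only gene and assay names were read: 7 OpenArray genes and 2 on the 7900HT (Gapdh and Pgk1 on both, with Eef1a1, Hprt1, Ppia, Rpl13a and Sdha on the OpenArray) have no fold change, and on the 7900HT 14 targets have 4 rows per gene and 25 have 2. Of 50 gene names, 47 matched a current symbol of the RefSeq table for GRCr8 and 3 an older one (Ccbl1, Cmkor1 and Mawbp). The sources used here name no build, so no coordinates are printed.

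Samples were put into groups by strain, treatment, dose and time from the labels, and each deposited value was joined to the group with the same strain, time and dose. The labels call replicates biological. The planned limma fits on values per animal could not be made with 1 deposited value per group. Tests with groups as units took their place, and they, unlike the gene lists and the naming rule, were chosen after the tables had been seen. Dose trends were tested by Spearman's rho of the log2 fold change against log10 dose over the 8 TCDD groups at 19 h, with all 40320 orders (5040 for 7 shared doses). Time courses were tested by the difference between the mean of the 100 µg/kg groups and the mean of the corn oil groups, with all 1287 splits in Han/Wistar and 84 in Long-Evans. Strain tests used Long-Evans minus Han/Wistar of matched groups. All tests were two-sided, needed at least 6 groups for a trend, and were adjusted by Benjamini-Hochberg over the targets of a strain and platform at 0.05. Correlations between platforms used 100000 permutations, whose smallest p is 1e-05. All p-values measure the spread between groups, and each dose or time is 1 group.

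The text names measured members of the fixed gene lists, the 10 called targets with the largest change at 100 µg/kg and 19 h per strain and platform, the 5 called targets with the largest strain difference at 19 h and at 240 h (none was called), the 3 targets with the highest and the 3 with the lowest correlation between platforms, the reference genes, and any target of a platform with few targets, which applied to the 7900HT. The part of the rule on corn oil strain differences, and the planned agreement of deposited with recomputed fold changes, gave nothing, because neither can be had without values per animal. Alternatives tried were centring on the mean or median of the group, centring each 7900HT gene set with 4 or 2 rows, joint adjustment, Pearson's r, corn oil as the lowest dose, leaving out single groups, and leaving out Ahrr and Aldh3a1.

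The procedures were tested on simulated data: panels of 49 or 39 targets took each platform's corn oil spread, with noise drawn independently for each target and group. With the OpenArray, 58% of 2-fold and 76% of 4-fold trends were called in Han/Wistar and 71% and 87% in Long-Evans, and 88% and 90%, and 81% and 88%, of time course shifts. With the 7900HT, 1% and 7% of the trends were called in Han/Wistar and 1% and 10% in Long-Evans, and 20% and 65%, and 4% and 6%, of time course shifts. At most 1.05% of unchanged targets were called. In the deposited data many targets of a group can shift together, so these rates may not hold for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.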

Results

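Liver RNA from rats of 2 strains was measured by quantitative PCR after a single oral dose of the dioxin TCDD or of the corn oil vehicle. Long-Evans rats are described in the labels as sensitive to TCDD and Han/Wistar rats as resistant. TCDD binds the aryl hydrocarbon receptor (AHR), a transcription factor that switches on genes of foreign-compound metabolism. The cDNA was run on the OpenArray, a plate of nanolitre wells with preloaded assays, and on the 7900HT, a conventional real-time PCR instrument. The labels give 150 OpenArray samples and 154 samples on the 7900HT, in 36 groups per platform with 3 to 7 samples each. Of the sample titles 150 are the same on both platforms, so the platforms are not independent. The dose arm was collected at 19 h and held 8 TCDD doses per strain, from 0.001 to 3000 µg/kg in Han/Wistar and from 0.001 to 1000 µg/kg in Long-Evans. The time arm followed 100 µg/kg at 1.5 to 384 h in Han/Wistar and at 3 to 240 h in Long-Evans, with corn oil groups at 5 and 3 of those times. The authors' deposited table of each platform holds 1 log2 fold change per gene and group, against corn oil at 19 h of the same strain, for 49 targets on the OpenArray and 39 on the 7900HT, with 38 targets on both. The log base is inferred, as no header states it. No value per animal was used, so the spread between animals and the number of amplified molecules behind a value are unknown. Groups were therefore the units of every test, and the corn oil groups at other times gave the background.

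The dose arm asks which genes respond to TCDD at 19 h and from which dose. On the OpenArray, Cyp1a1, Nqo1 and Tiparp rose with dose in both strains and Inmt fell. Cyp1a1, the classical AHR target, stood at 1.91 log2 units at 0.01 µg/kg, 7.02 at 0.1 µg/kg and 9.99 at 100 µg/kg in Han/Wistar in the authors' deposited table, and at 1.32, 6.45 and 9.47 in Long-Evans. Nqo1, a quinone reductase, reached 3.78 in Han/Wistar and 3.47 in Long-Evans at 100 µg/kg in the authors' deposited table, and Tiparp, a feedback repressor of AHR, reached 3.02 and 3.11. Inmt, an indolamine methyltransferase, stood at -4.47 in Han/Wistar and -3.95 in Long-Evans at 100 µg/kg in the authors' deposited table. As background, the corn oil groups at other times spanned -1.48 to 3.47 for Cyp1a1 and 0.45 to 1.53 for Inmt in Han/Wistar in the authors' deposited table.

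Of the AHR battery fixed before the data were examined, 12 members were measured. In Han/Wistar on the OpenArray 9 of the 12 passed a two-sided exact permutation test of Spearman's rho against log10 dose over 8 groups, with Benjamini-Hochberg adjustment. Of these 6 rose, namely Aldh3a1, Cyp1a1, Cyp1b1, Nfe2l2, Nqo1 and Tiparp, and Fmo1, Inmt and Ugt1a1 fell. In Long-Evans 11 of 12 passed, where 8 rose (those 6, Ahrr and Exoc3) and the same 3 fell. Cyp1a2 missed the threshold in both strains (rho 0.74, adjusted exact permutation p = 0.0642 in Han/Wistar and 0.0548 in Long-Evans), at 4.30 and 3.88 log2 units at 100 µg/kg in the authors' deposited table. Adjusted over the list alone, 11 members passed in Han/Wistar and 12 in Long-Evans. Of the AHR signalling list, Ahr itself had a rho of 0.57 in Han/Wistar (adjusted exact permutation p = 0.168) and 0.76 in Long-Evans (adjusted exact permutation p = 0.0462), and the sign in Long-Evans turned to -0.76 when each group was centred on its mean. No member of the lists for circadian, lipid, glucose, other drug, stress or cell cycle genes, or of other cell types, was on either platform.

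**Figure D1:**
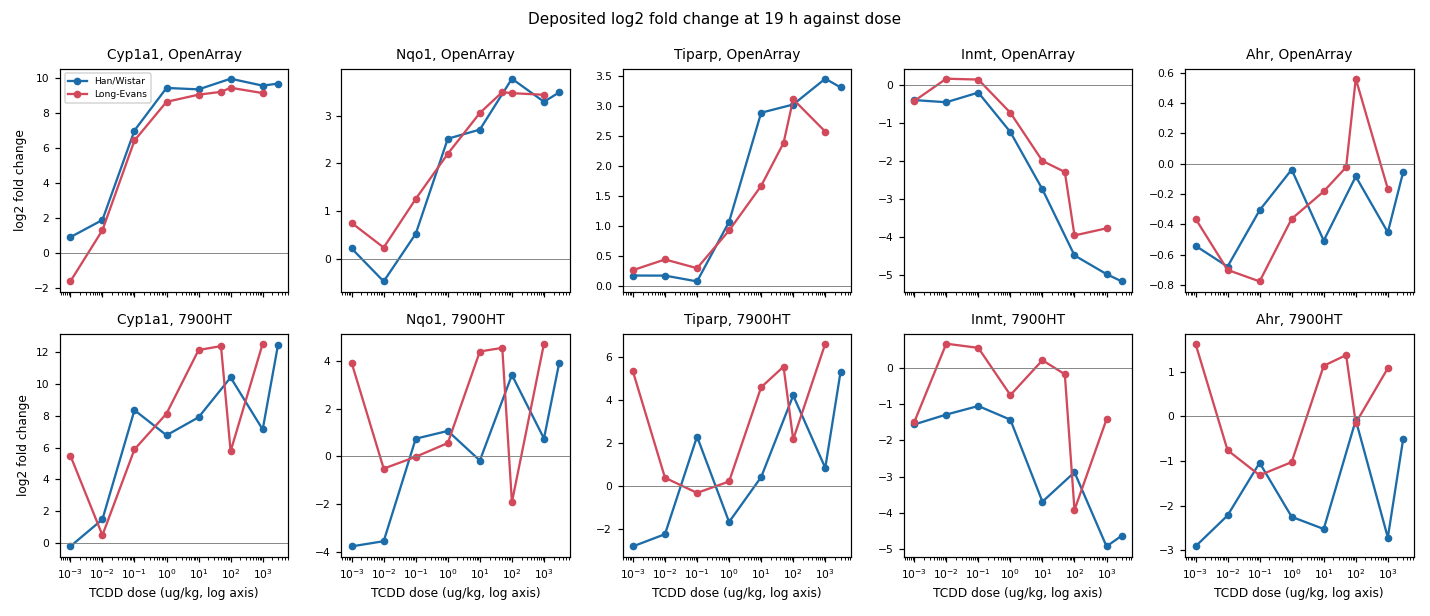
Log2 fold change at 19 h (vertical axis) against TCDD dose in µg/kg on a log axis for Cyp1a1, Nqo1, Tiparp, Inmt and Ahr, with the OpenArray in the upper row and the 7900HT in the lower row. Each point is the single value per group of the authors' deposited table, so no error bars can be drawn, and on the OpenArray Cyp1a1 at 100 µg/kg reaches 9.99 in Han/Wistar and 9.47 in Long-Evans.

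Over all 49 OpenArray targets, 29 passed in Han/Wistar (19 higher with dose, 10 lower) and 39 in Long-Evans (26 higher, 13 lower). Of these 19 rose and 9 fell in both strains, against 10.1 and 2.65 expected of independent lists, and none went opposite ways. Among the named targets, Ccbl1, an enzyme of cysteine conjugate cleavage now called Kyat1, stood at 1.56 in Han/Wistar and 2.15 in Long-Evans at 100 µg/kg in the authors' deposited table, Pmm1, a phosphomannomutase, at 1.22 and 1.33, and Mawbp, now called Pbld1, at 1.23 and 1.25. Scn4b, a sodium channel subunit, had a rho of 0.90 in Long-Evans (adjusted exact permutation p = 0.0102) and of 0.75 in Han/Wistar (adjusted exact permutation p = 0.0902), and stood at 7.14 and 5.03 at 100 µg/kg in the authors' deposited table. For Cyp1a1 the rho was 0.90 in Han/Wistar (exact permutation p = 0.00456, adjusted 0.0160) with a Pearson r of 0.87 (exact permutation p = 0.00062), and the rho was 0.89 without the 2 doses farthest from the median. For Inmt in Long-Evans the rho was -0.90 (exact permutation p = 0.00456, adjusted 0.0102), Pearson r was -0.89 (exact permutation p = 0.00446), and the rho without those 2 doses was -0.94. Of the called targets, 29 in Han/Wistar and 38 in Long-Evans kept an absolute rho of at least 0.5 with its sign without those doses.

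The split into higher and lower depended on the scaling, because the mean and the median over targets themselves rose with dose. Centring each group on its mean over the targets listed in every group, a shift of 0.86 in Han/Wistar and 1.12 in Long-Evans at 100 µg/kg and 19 h, gave 8 higher and 20 lower in Han/Wistar and 9 higher and 21 lower in Long-Evans, and centring on the median gave 14 and 17, and 17 and 17. The calls rested in part on the group at 1 µg/kg, without which 7 targets passed in Han/Wistar and 24 in Long-Evans.

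On the 7900HT 1 of 39 targets passed in Han/Wistar, Cyp1b1, a dioxin-inducible P450 enzyme (rho 0.95, exact permutation p = 0.00114, adjusted 0.0445; Pearson r 0.94, exact permutation p = 0.00131, adjusted 0.0513), and it stood at 7.86 at 100 µg/kg in the authors' deposited table against -3.90 to 5.41 in the other corn oil groups. In Long-Evans no target passed the exact permutation test, 5 had an unadjusted p under 0.05, and Pearson's r called 0. Centring each set of genes with 4 or 2 rows gave 4 calls in Han/Wistar and 9 in Long-Evans (4 higher, 5 lower), centring on the group median gave 6 and 3, and centring on the group mean gave 6 and 0. Ahrr, which encodes the AHR repressor, lay at -5.45 in Han/Wistar and -9.11 in Long-Evans at 100 µg/kg on the 7900HT and at 4.95 and 7.86 on the OpenArray in the authors' deposited table. Its corn oil groups on the 7900HT spanned -10.89 to 7.02 in Han/Wistar in the authors' deposited table. Of the battery 1 member passed in Han/Wistar and 0 in Long-Evans, and adjusted over the list alone 2 and 0. Of the signalling list, Arnt, the partner of AHR, had a rho of 0.81 in Han/Wistar and 0.24 in Long-Evans (adjusted exact permutation p = 0.136 and 0.690), and Ahr had 0.38 and 0.07 (0.610 and 0.930). Panels were simulated with each platform's corn oil spread and with noise independent between targets, whereas real groups can shift many targets together. With the spread of the 7900HT, 7% of 4-fold trends were called in Han/Wistar and 10% in Long-Evans, against 76% and 87% with that of the OpenArray.

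**Figure D2:**
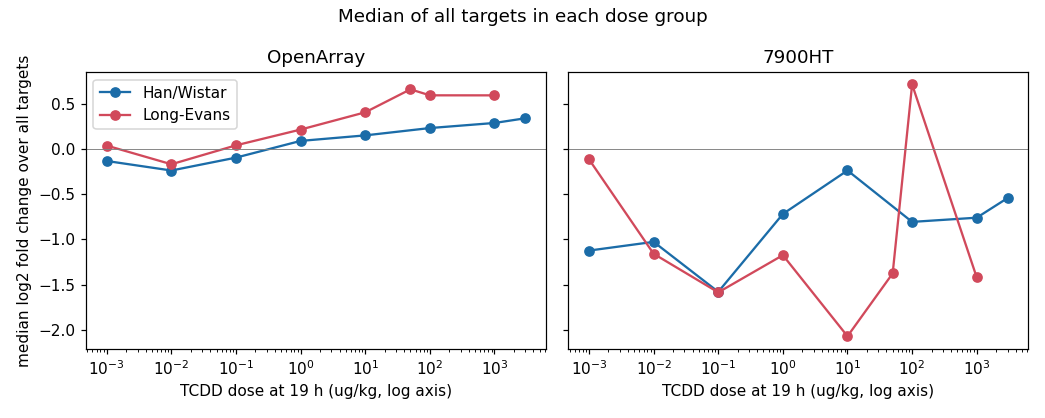
Median log2 fold change over all targets (vertical axis) in each TCDD dose group at 19 h against dose in µg/kg on a log axis, for the OpenArray (left) and the 7900HT (right). Each point is the median of the values in the authors' deposited table, and in Long-Evans on the 7900HT the group at 100 µg/kg lies at 0.71 between -1.38 at 50 µg/kg and -1.42 at 1000 µg/kg.

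The time arm asks how the response to 100 µg/kg develops. On the OpenArray, Cyp1a1 already stood at 5.63 at 1.5 h in Han/Wistar and at 7.85 at 3 h in Long-Evans in the authors' deposited table, and at 9.84 and 9.29 at 240 h. Its corn oil group at 1.5 h in Han/Wistar was also at 3.47 in the authors' deposited table, which leaves 2.16 between the groups at that time. Cyp1b1 stood at 4.60 at 3 h, 10.62 at 19 h and 13.74 at 384 h in Han/Wistar in the authors' deposited table, and at 2.81, 9.60 and, at 240 h, 12.28 in Long-Evans. Relative to corn oil of the same time in Han/Wistar it differed by 2.68 at 1.5 h, 8.74 at 96 h, 8.39 at 240 h and 14.84 at 384 h, and no test compared the timing of genes. Cmkor1, a chemokine scavenging receptor now called Ackr3, stood at 6.73 in Long-Evans and 2.67 in Han/Wistar at 240 h in the authors' deposited table, and Fmo1, a flavin monooxygenase, at -5.28 and -1.96.

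The mean of the TCDD groups was compared with the mean of the corn oil groups by a two-sided exact permutation test, with 8 against 5 groups in Han/Wistar and 6 against 3 in Long-Evans. On the OpenArray 27 of 49 targets passed in Han/Wistar (26 higher, 1 lower) and 16 in Long-Evans (15 higher, 1 lower), where 30 had an unadjusted p under 0.05 and the smallest p the 84 splits allow is 0.0119. Of the battery 10 members passed in Han/Wistar and 7 in Long-Evans, and adjusted over the list alone 10 and 8. Ahr differed by 0.58 in Han/Wistar (adjusted exact permutation p = 0.0281) and by 0.72 in Long-Evans (0.312), and by -0.44 in Han/Wistar after centring on group means. The differences on the log2 scale were 8.37 for Cyp1a1 (adjusted exact permutation p = 0.00952), 3.32 for Nqo1 (0.0104) and -3.15 for Inmt (0.0254) in Han/Wistar, and 8.19 (0.0365), 4.02 (0.0365) and -3.73 (0.0941) in Long-Evans. Centring each group on its mean turned the split to 8 higher and 27 lower in Han/Wistar and to 9 and 19 in Long-Evans, and centring on the median gave 16 and 12, and 11 and 7. The groups at 3, 6 and 10 h have no corn oil group of their own time, and leaving out any 1 corn oil group, or the TCDD group at 6, 10, 19 or 96 h, left 0 targets in Long-Evans, where the remaining splits are fewer.

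On the 7900HT 14 of 39 targets passed in Han/Wistar (6 higher, 8 lower), and 4 to 16 with 1 group left out. Cyp1a1 differed by 10.63 log2 units (adjusted exact permutation p = 0.0101), Pmm1 by 3.34 (0.0101), Nqo1 by 3.66 (0.0364) and Ern1, an endoplasmic reticulum stress sensor, by -2.53 (0.0101). Uvrag differed by -1.93 (adjusted exact permutation p = 0.0265) and Cyb5a by -2.48 (0.0253). On the OpenArray they had the opposite sign in Han/Wistar, at 0.81 (adjusted exact permutation p = 0.0104) and 0.36 (0.0625). The remaining called targets had the same sign on both platforms, but a shared sign is weak evidence for several of them. Ern1, Glud1, Ivns1abp, Lasp1 and Sdc1 differed by only -0.11, -0.45, -0.27, -0.20 and -0.29 on the OpenArray. None of these passed there (adjusted exact permutation p = 0.668, 0.143, 0.415, 0.198 and 0.198). All targets called lower on the 7900HT except Inmt have 2 rows per gene, and the gene sets with 2 and 4 rows moved apart there, as described below. Of the battery 5 members passed, and adjusted over the list alone 5. In Long-Evans 0 passed the exact permutation test and 16 had an unadjusted p under 0.05, among them Cyp1a1 with a difference of 7.75 (exact permutation p = 0.0119, adjusted 0.0663). Adjusted over the list alone, 3 battery members passed in Long-Evans. With group means as the centre, 10 targets passed there, and when both strains were adjusted together 5 passed in Han/Wistar.

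**Figure D3:**
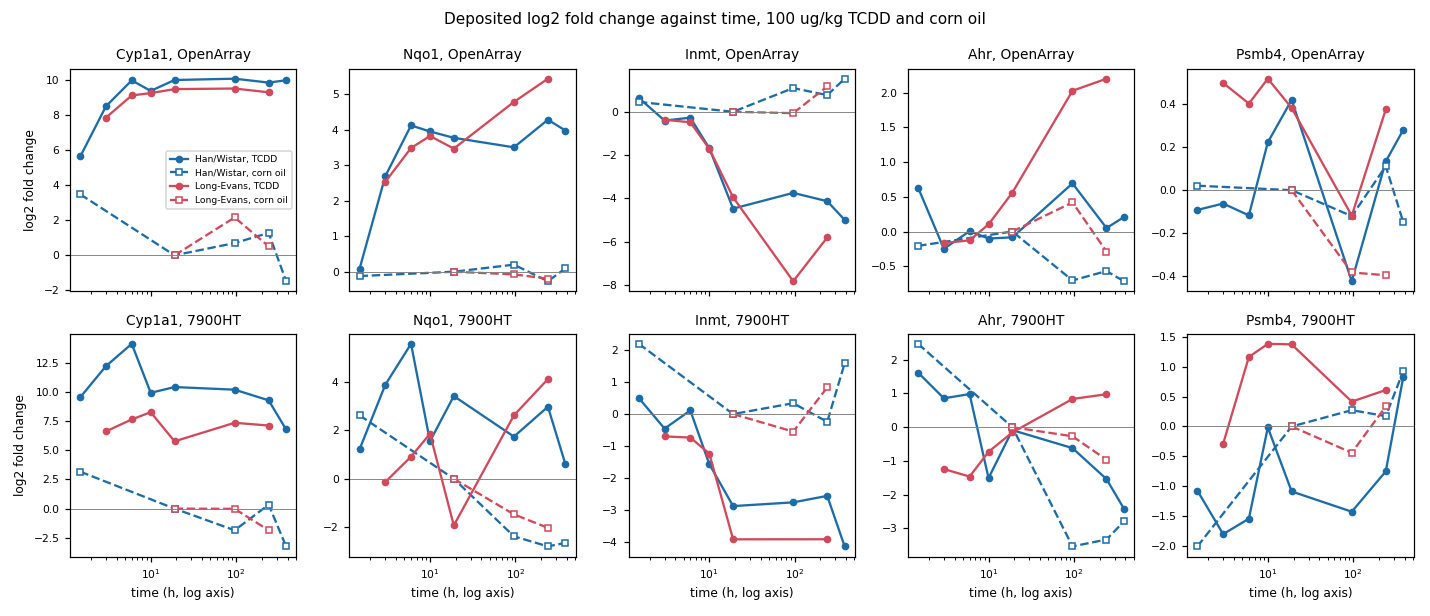
Log2 fold change (vertical axis) against hours after dosing on a log axis for Cyp1a1, Nqo1, Inmt, Ahr and Psmb4, with TCDD at 100 µg/kg as filled circles and corn oil as open squares. Each point is the single value per group of the authors' deposited table without error bars, and Inmt in Long-Evans on the OpenArray lies at -7.83 at 96 h.

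The strains were compared through the difference Long-Evans minus Han/Wistar of matched groups. At 100 µg/kg and 19 h their OpenArray values correlated across the 49 genes (Pearson r 0.97, Spearman rho 0.95; genes are not independent replicates), and on the 7900HT the values were 0.62 and 0.62 across 39 genes. At 96 h they were 0.95 and 0.94 on the OpenArray and 0.73 and 0.83 on the 7900HT, and at 240 h 0.95 and 0.91, and 0.88 and 0.90. Relative to corn oil of the same time on the OpenArray, the 5 widest gaps between the strains at 240 h were in Aldh3a1 (14.10 in Long-Evans and 8.07 in Han/Wistar), Cyp1b1 (13.22 and 8.39), Cmkor1 (6.38 and 2.56), Fmo1 (-5.53 and -1.78) and Ahrr (11.68 and 8.29). For Aldh3a1, Cyp1b1 and Ahrr corn oil at 240 h stood at -3.26, -0.95 and 0.00 in Long-Evans and 2.62, 5.05 and 2.29 in Han/Wistar in the authors' deposited table. These values are changes from corn oil at 19 h of the same strain. Long-Evans minus Han/Wistar of this corn oil change was thus -5.89, -6.00 and -2.29, against strain gaps of 6.03, 4.84 and 3.40. All of the gap for Cyp1b1, nearly all for Aldh3a1 and much of it for Ahrr therefore lies in the change of corn oil between 19 and 240 h. Whether corn oil at 19 h or at 240 h differs between the strains cannot be told from such values. On the 7900HT the difference Long-Evans minus Han/Wistar at 240 h was -4.59 for Aldh3a1, 3.85 for Cyp1b1, 5.41 for Cmkor1 and -3.08 for Fmo1, and Ahrr has no value. These 5 were chosen after their values were seen, and their strain tests over the OpenArray time course gave unadjusted exact permutation p = 0.571, 0.321, 0.298, 0.0952 and 0.0119.

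With the values as deposited, no strain difference passed adjustment by Spearman's rho over doses or by the time course test. Over the 7 shared doses, 0 targets passed the exact permutation test of Spearman's rho of the difference on either platform, with 5 of 48 tested at an unadjusted p under 0.05 on the OpenArray and 0 of 37 on the 7900HT, and Pearson's r called 1, Lasp1, and 0. With each set of genes with 4 or 2 rows on the 7900HT centred apart, 3 passed there, all with a falling difference. Over the time course, with 6 TCDD against 3 corn oil groups, 0 passed on either platform and 6 and 8 had an unadjusted p under 0.05. The smallest p the 84 splits allow is 0.0119, so a strain difference in few targets could not pass. The dose test sees only a difference that rises or falls with dose, and the time test averages the groups from 3 to 240 h. A difference that is constant over doses, or present only at late times, can be missed, so the lack of calls does not show equal responses. Whether the strains differ in the level of a gene in corn oil was not analysed here, because each strain's values are relative to its own corn oil group at 19 h.

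The platforms were compared over the 38 shared targets. Where the OpenArray value at 100 µg/kg was at least 2-fold from control, the 7900HT value had the same sign for 95 of 111 gene and group pairs in Han/Wistar (85.6%, 95% exact binomial interval 77.6 to 91.5) and for 94 of 109 in Long-Evans (86.2%, 78.3 to 92.1). The pairs share animals, groups and controls, so the intervals are too narrow. Of these pairs 81 of 97 higher and 14 of 14 lower on the OpenArray had the same sign in Han/Wistar, and 81 of 96 and 13 of 13 in Long-Evans. Of all 7900HT values of these groups 54.6% were below 0 in Han/Wistar and 37.4% in Long-Evans, so a sign can match without any link between the platforms, and no test against that was made. Inmt, Ccbl1, Cyp1b1 and Cmkor1 correlated between platforms over the 12 Han/Wistar groups at 1 µg/kg or more, with Spearman's rho of 0.93, 0.91, 0.90 and 0.85 (adjusted permutation p = 0.00114, 0.00114, 0.00165 and 0.00940). Their Pearson r was 0.94, 0.80, 0.89 and 0.77 (permutation p = 2.0e-05, 0.00017, 0.00036 and 0.00296), and 0.88, 0.69, 0.89 and 0.66 without the 2 groups farthest from the median. Gfer, Cyp1a2 and Nfe2l2 were lowest, at -0.44, -0.20 and -0.13 (permutation p = 0.155, 0.542 and 0.684). In Long-Evans over 10 groups Cyb5a, Cyp1b1 and Pmm1 were highest at 0.89, 0.87 and 0.85 (adjusted permutation p = 0.0331 for each) and Ugt1a1, Psmb4 and Eml4 (9 groups) lowest at -0.59, -0.43 and -0.32 (permutation p = 0.0792, 0.220 and 0.410). In all 4 of 38 targets passed in Han/Wistar and 7 in Long-Evans, with median rho of 0.38 and 0.51.

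Corn oil groups varied more on the 7900HT. The median SD over corn oil groups was 0.21 log2 units on the OpenArray and 0.97 on the 7900HT in Han/Wistar (5 groups), and 0.16 and 0.78 in Long-Evans (3 groups), and 37 and 35 of 38 targets had the larger SD on the 7900HT. The median ratio in Han/Wistar of 5.20 fell to 1.89 when the genes with 4 and with 2 rows each in the 7900HT table were centred apart, and in Long-Evans it went from 3.61 to 3.13. Across genes, the median Spearman rho between platforms was 0.57 over the Han/Wistar groups at 1 µg/kg or more and 0.31 over the 6 other groups with corn oil or at most 0.01 µg/kg, and 0.56 and 0.14 in Long-Evans.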

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

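The tests of patterns in this part and the p under 0.05 used to list strain differences were chosen after the results were seen, and the counts over regroupings were planned before they were run. The strain differences below had an unadjusted exact permutation p under 0.05 by Spearman's rho or the time course test, and none passed adjustment in those tests. By Pearson's r Lasp1 passed on the OpenArray (r -0.95, adjusted exact permutation p = 0.0381). On the OpenArray 5 of 48 tested dose trends and 6 of 49 time courses did so, against 2.4 and 2.45 expected by chance, and on the 7900HT 0 of 37 and 8 of 39, against 1.85 and 1.95.

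Over the 7 shared doses on the OpenArray, the rho of Long-Evans minus Han/Wistar was 0.89 for Aldh3a1, an aldehyde dehydrogenase. It was 0.79 for Cyp1a1, 0.82 for Exoc3, -0.96 for Lasp1, a cytoskeletal adaptor, and -0.79 for Nrbp2. A positive rho means that the difference rose with dose, not that Long-Evans stood higher. At 100 µg/kg and 19 h the difference was -0.91 for Aldh3a1, -0.52 for Cyp1a1, 0.29 for Exoc3, 0.07 for Lasp1 and -0.35 for Nrbp2. On the 7900HT the rho was -0.36 for Aldh3a1, -0.14 for Cyp1a1, -0.29 for Exoc3 and -0.14 for Lasp1, and Nrbp2 was not measured. Over the time course on the OpenArray, the TCDD minus corn oil difference in Long-Evans exceeded that in Han/Wistar by 3.31 log2 units for Ahrr, 0.30 for Gfer, 0.33 for Pomp, 0.57 for Psmb4 and 1.71 for Scn4b, and was -0.62 for Glud1, glutamate dehydrogenase. Part of each comes from the corn oil groups. Their Long-Evans minus Han/Wistar values spanned -2.29 to 0 for Ahrr, -0.21 to 0 for Gfer and -0.15 to 0 for Pomp. For Psmb4, Scn4b and Glud1 they spanned -0.51 to 0, -2.94 to 0.24 and 0 to 0.33. On the 7900HT the differences were -3.78 for Cyp1a1, -2.43 for Cyp1a2, 2.49 for Gfer, 1.79 for Pde2a, 2.84 for Pomp, 2.07 for Psmb4, 2.11 for Tpm1 and 1.97 for Uvrag. Their OpenArray differences, where not flagged, were -0.78 for Cyp1a1, -0.66 for Cyp1a2, 0.44 for Pde2a, -0.06 for Tpm1 and 0.16 for Uvrag. Ahrr and Glud1 differed by 9.79 and 0.21 on the 7900HT without being flagged there, and Scn4b was not measured. Of the targets flagged on the 7900HT, Cyp1a1, Cyp1a2 and Gfer have 4 rows per gene there, and Pde2a, Pomp, Psmb4, Tpm1 and Uvrag have 2. These gene sets moved apart on that platform, as described below. An offset of a whole set was not told apart from a strain difference in single genes. Pomp and Psmb4 encode a proteasome assembly factor and a proteasome subunit. With Gfer they are on both lists, 3 of the 38 shared targets against 1.05 expected of independent lists, but 150 sample titles are the same on both platforms, so the lists are not independent.

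Regrouping asked how often counts as large arise. Dose orders gave as many calls as the real one in 1 of 100 draws (the real one) on the OpenArray, under the 5% set beforehand. The counts were 29 calls against at most 17 in Han/Wistar and 39 against at most 37 in Long-Evans. In Long-Evans other orders came close, so counts as large were rare but chance is not excluded. On the 7900HT 2 of 100 gave at least the 1 call in Han/Wistar, the highest other giving 1, which is under the 5% set beforehand. That single call, Cyp1b1, was lost under joint adjustment, with Pearson's r, with corn oil as the lowest dose and without any 1 of the 8 doses, so it is not secure. For the time course, 1 of 100 splits reached the 27 calls on the OpenArray in Han/Wistar (highest other 26), 1 of 84 the 16 in Long-Evans (14) and 1 of 100 the 14 on the 7900HT in Han/Wistar (1). Each share is under the 5% set beforehand, but on the OpenArray other splits came close, so chance is not excluded for that platform. With 1 group left out the counts ranged over 20 to 29, 0 to 21 and 4 to 16. For the strain differences, counted at an unadjusted p under 0.05 because 0 passed adjustment, 9 of 100 dose orders gave at least 5 (highest other 7) and 9 of 84 splits at least 6 (17) on the OpenArray, and 5 of 84 splits at least 8 (16) on the 7900HT, so chance cannot be excluded for these 3. Where the real count is 0, every regrouping reaches it by construction and nothing is decided: all 100 for the Long-Evans dose response (highest other 2), all 84 for the Long-Evans time course (0) and all 100 for the strain dose trend (25), each on the 7900HT.

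On the 7900HT the 13 shared genes with 4 rows and the 25 with 2 rows moved apart in groups with no or little TCDD. In Han/Wistar corn oil at 1.5 h the medians were 2.31 and -1.46, and on the OpenArray -0.24 and -0.31. The SD of the gap over 10 such groups was 2.03 on the 7900HT and 0.22 for the same genes on the OpenArray. A difference in the animals between these gene sets would have to appear on the OpenArray, and it did not at that size. Separate runs or separate normalization of the gene sets may account for the gap and stay open, since no run is given in the labels.

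In Long-Evans on the 7900HT the 38 targets at 100 µg/kg and 19 h departed from the mean of 50 and 1000 µg/kg by a median of 1.46 (quartiles -1.62 and 3.20). On the OpenArray the same targets departed by a median of 0.24 (quartiles -0.07 and 0.46), which argues against a peak of the response at that dose. On the 7900HT 100% of the targets at 100 µg/kg lay nearer to the 6 and 10 h groups than to those 2 doses, and on the OpenArray 36.8% did. A candidate explanation is that dose and time groups were run apart on the 7900HT, but no label gives the run.

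On the OpenArray the median of all 49 targets at 96 and 240 h was 0.99 above corn oil of those times in Long-Evans and 0.61 in Han/Wistar. A shift of the reference genes would raise every target alike. The 10 Long-Evans targets without a called dose trend at 19 h shifted by a median of 0.15 (quartiles -0.00 and 0.47). The 8 of them with an unadjusted p of at least 0.05 had the same median (quartiles -0.29 and 0.37). Cyp1a2, among the 10, shifted by 3.38 and Mug1 by -1.43. These values cannot decide whether the reference genes shifted, because the 10 targets are not shown to be unresponsive to TCDD. By Pearson's r, 45 of the 49 targets had a called dose trend in Long-Evans. Of the 10 it left only Cyp2s1, Psmb4 and Tpm1 uncalled (adjusted exact permutation p = 0.778, 0.0730 and 0.0637). A shift of the reference genes, as the whole cause or a part of it, stays open. The difference between the strains stays open: on the 7900HT 61.5% of targets (24 of 39) had the higher late shift in Long-Evans, too few to decide.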

How the results depend on the processing

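Alternatives other than the planned mean centring, joint adjustment and shared-target centring were chosen after the data were seen. Over settings other than leaving out a group, 53 of 70 counts and shares stayed near the main value in size, and 227 of 262 values of named targets kept their sign and their call. With 1 group left out, 84 of 108 counts stayed near in size and 456 of 633 named values kept their call, while 177 lost it with the same sign. The 53 and the 84 include counts of 0 that stayed at 0. With 1 group left out these were all strain tests and both Long-Evans tests on the 7900HT, where fewer permutations leave little room for a call. A count near in size can hold other targets: mean centring turned 26 higher and 1 lower in the Han/Wistar time course on the OpenArray to 8 and 27, with 14 of the 27 calls shared, and 19 and 10 in the dose response to 8 and 20, with 20 shared. Mean centring moved the calls for the time course in Long-Evans on the OpenArray from 16 to 28, for the dose response in Han/Wistar on the 7900HT from 1 to 6, and for the time course in Long-Evans on the 7900HT from 0 to 10. Median centring gave 6 and 10 for those last and 3 for the dose response in Long-Evans on the 7900HT. Centring each 7900HT gene set gave 4 dose calls in Han/Wistar, 9 in Long-Evans and 3 strain dose trends, an SD ratio of 1.89 in Han/Wistar and 76.1% same sign in Long-Evans. Joint adjustment gave 0 dose and 5 time calls in Han/Wistar on the 7900HT, Pearson's r and corn oil as the lowest dose each 0 dose calls there, and Pearson's r 1 strain dose trend on the OpenArray. Without Ahrr and Aldh3a1, 91.6% of Han/Wistar pairs had the same sign. Mean centring reversed Ahr in the Han/Wistar time course (-0.44) and the Long-Evans dose trend (-0.76; -0.21 with the median) and Mawbp in the Long-Evans dose trend (-0.31), all on the OpenArray. The subtracted mean was itself higher after TCDD, so a target that rose less than the mean can turn negative by arithmetic. In Long-Evans on the OpenArray at 19 h the mean was -0.39 at 0.01 µg/kg and 1.12 at 100 µg/kg. Which scaling is closer to the RNA levels was not tested.

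Leaving out 1 group at a time gave 7 to 28 dose calls in Han/Wistar and 24 to 42 in Long-Evans on the OpenArray, with the fewest without 1 µg/kg, and 0 in both strains on the 7900HT. All strain tests stayed at 0. The time course gave 20 to 29 calls in Han/Wistar and 0 to 21 in Long-Evans on the OpenArray and 4 to 16 in Han/Wistar on the 7900HT, fewest without corn oil at 240 h, and 0 in Long-Evans. Fewer groups leave fewer permutations, and the smallest p then rises.

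No paired analysis was possible because the deposited values are 1 per group and carry no replicate number. For the same reason leaving out animals, tests over animals, other handling of undetermined wells or well averages, single reference genes, spread per contrast and animals on both platforms alone were not run. All corn oil groups as controls changes no test by construction, the planned detection filter removes no target, and platform correlation over corn oil groups alone has too few groups. The number of amplified molecules is unknown, so no depth limit can be given.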

Other observations

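Corn oil groups themselves differed between times, and these values were looked at after the tables had been seen. On the OpenArray in Han/Wistar, Cyp1b1 stood at 4.38 at 96 h and 5.05 at 240 h but at -0.59 at 1.5 h and -1.10 at 384 h in the authors' deposited table. Aldh3a1 stood at 1.38 and 2.62 at 96 and 240 h and at -3.33 and -3.54 at 1.5 and 384 h in the authors' deposited table. In Long-Evans at 96 h Cyp1b1, Scn4b and Cyp1a1 stood at 2.79, 2.06 and 2.16 in the authors' deposited table. On the 7900HT Aldh3a1 in Han/Wistar corn oil at 384 h was listed at 23.00 in the authors' deposited table.

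Cyp2a1, a P450 enzyme outside the fixed lists and named after its values were seen, stood at 2.40 at 384 h in Han/Wistar and at 3.77 at 96 h in Long-Evans on the OpenArray in the authors' deposited table, and at 0.06 at 1.5 h in Han/Wistar. Fdft1, which makes squalene, stood at -2.38 at 240 h in Long-Evans and at -0.85 in Han/Wistar on the OpenArray in the authors' deposited table.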
